A study of Mus musculus with 2 samples.

How the data were processed

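Gene expression was measured in monocytes from mouse spleen on 1-colour Agilent microarrays. The strain was ICR, an outbred mouse stock. The cells were sorted by flow cytometry with antibodies to CD11b and Ly6C at 8 weeks after a sham operation or a 5/6 nephrectomy, per the labels. A 5/6 nephrectomy (5/6Nx) removes most of the kidney tissue and is used to model chronic kidney disease. Total RNA was amplified, labelled with the dye Cy3 and hybridised, 1 array per group, per the labels' protocols. Both arrays lay on the same slide and went through the same scan, per the file headers. How many mice stood behind each RNA sample is not given in the sources used here.

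The deposited scanner files hold linear intensity values from Agilent Feature Extraction. The submitters' processing notes give version 9.5.1.1 of this software, whereas the parameter block of the files gives 10.7.1.1. Per the file headers, the processed intensity is the spot signal after background subtraction with a spatial and a multiplicative detrending within each array, and the values carry no scaling between arrays. Low spots carry a surrogate value, per the file headers. Each array has 62976 spots, of which 59305 are not controls and represent 56605 probes. The authors' value table holds linear intensity values of 52145 probes, with medians of 47.5 for the sham array and 48.2 for the 5/6Nx array. Its columns share their lowest value, 2.64, and their highest value, 522269, and the sorted columns differ by 0.339% at the median. In log2 units it correlated with the scanner intensities at a Pearson r of 0.9996 for the sham array and 0.9998 for the 5/6Nx array, across probes. These values are uncentred and on a linear scale, and the normalization that the authors applied to them is not given in the sources used here.

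The main values were log2 of the processed intensity minus the array's 75th percentile over non-control spots without an outlier flag, which was an intensity of 439.2 for the sham array and 544.5 for the 5/6Nx array. A log2 value of 0 thus marks a spot as bright as its array's 75th percentile. Spots with an outlier flag on either array were left out, 41 on the sham array and 47 on the 5/6Nx array, and no spot was saturated. Spots of one probe were averaged. A probe was measured when the software called it well above background on both arrays, and a gene was represented by its brightest measured probe. Probes were named through their accession (32992 probes), symbol (10224) or synonym (520) in a RefSeq table of the assembly GRCm38.p6, which served for names only. The other 12867 probes kept the name in the files and were counted apart. Probe positions are those in the files, on the mouse build mm9, and exon or UTR annotation on that build was not used here. Among 1379 genes at least 2-fold apart with several measured probes, 168 had probes that differed in sign.

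Genes well above background on 1 array and on no probe of the other array were given as bounds. The bound is the bright value minus the higher of the dim probe's own value and the lowest value of any probe well above background on the dim array, which was an intensity of 12.8 on the sham array and 13.7 on the 5/6Nx array. No bound was given for 111 genes where it came to less than 1-fold.

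With 1 array per group there is no replicate error, so no p-value was computed and nothing was tested across animals. Counts of genes use a difference of at least 2-fold. The spread between spots of one probe was taken from 283 probes with at least 8 usable spots of the 10 printed. Its SD was 0.0557 in log2 units on the sham array and 0.0496 on the 5/6Nx array, and 0.0746 for a difference of single spots. These probes are bright, so this noise leaves out dim probes, labelling, sorting and the animals. The number of arrays limits the precision.

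Gene lists were fixed before the data were examined, with 4 primary lists, 20 other lists and 15 cell type marker lists. The median difference of a list was set against 10000 random lists of the same number of measured genes, matched on mean signal in 20 bins. The percentile among these describes these arrays and is not a test of the operation. A list is called above or below the random range when its percentile is over 97.5 or under 2.5. Lists with fewer than 3 measured genes have no percentile. The genes named were also chosen by a rule set in advance. In each direction it takes the 12 genes with the largest difference among genes at least 2-fold apart, with a mean signal above the median of measured genes and with all measured probes on one side. It leaves out immunoglobulin and T cell receptor segments and names that are no gene symbols. It adds the 5 genes with the largest bound in each direction, the sort antigens, the 2 to 4 measured members of each list with the largest differences, and the measured clock genes. Some of the genes this rule takes, and a list, are not reported here.

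The steps were tested on simulated data. In simulated arrays with a log2 noise of 0.1 per spot, 200 of 16150 genes carried planted differences of 1.5 or 3 in log2 units, in either direction. All 50 genes of each size and direction were called on the right side, and none of the 15950 other genes was called. Both simulated arrays were drawn from the sham signal, with equal noise for bright and dim spots and the same background calls. They thus lack the noise of dim spots, genes found on 1 array only and differences between samples, and say nothing about wrong calls from these. Of 100 random lists of 20 measured genes, 5 fell outside the random range, and of 10 lists with a planted difference of 1, all 10 lay above it.

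Alternatives fixed before the data were examined were normexp background correction with an offset of 50, scaling to the median, to the 75th percentile of probes well above background, to the spike-in probes, by quantiles or by cyclic loess, 3 other filters on dim probes, the mean over a gene's probes, flagged spots kept, and the authors' value table. Adding the one-array genes at their bound was chosen after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.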

Results

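Splenic monocytes of ICR mice were profiled at 8 weeks after a sham operation or a 5/6 nephrectomy (5/6Nx), with 1 array per group. On the sham array 37333 of 59305 non-control spots (63.0%) were well above background, and on the 5/6Nx array 39735 (67.0%). The comparison asks how the loss of kidney tissue bears on gene expression in monocytes of the spleen. All differences below are 5/6Nx minus sham in log2 units, and none has a replicate check.

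Interferon-stimulated, cytokine and MHC class II genes were higher on the 5/6Nx array, with list medians of 5.70, 3.75 and 2.65, and antioxidant and glucocorticoid-responsive genes were lower, with list medians of -1.29 and -1.03. Among genes measured on both arrays, the named genes with the largest differences upward were Cfb, the complement factor B, at 12.35, and Tgtp2, an interferon-induced GTPase, at 10.99. The named genes measured on both arrays with the largest differences downward were Fn1, the matrix protein fibronectin, at -8.20, and Cgnl1, a junction protein, at -7.74. Markers of T cells and NK cells were also higher on the 5/6Nx array, with list medians of 4.71 and 3.35. Of 15715 genes measured on both arrays, 1923 were at least 2-fold higher and 1721 at least 2-fold lower, so that 52.8% of the genes apart were higher. This share was 40.7% with median scaling and 79.5% with spike-in scaling. The median of all measured genes was -0.12. Differences of at least 8-fold were found upward in 399 genes and downward in 167. A further 1485 genes were well above background on the 5/6Nx array only, 583 of them with a bound of at least 2-fold, against 419 on the sham array only, 165 of them at least 2-fold. Among 6566 transcripts that could not be matched to the RefSeq table, 697 were higher and 441 lower.

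**Figure D1:**
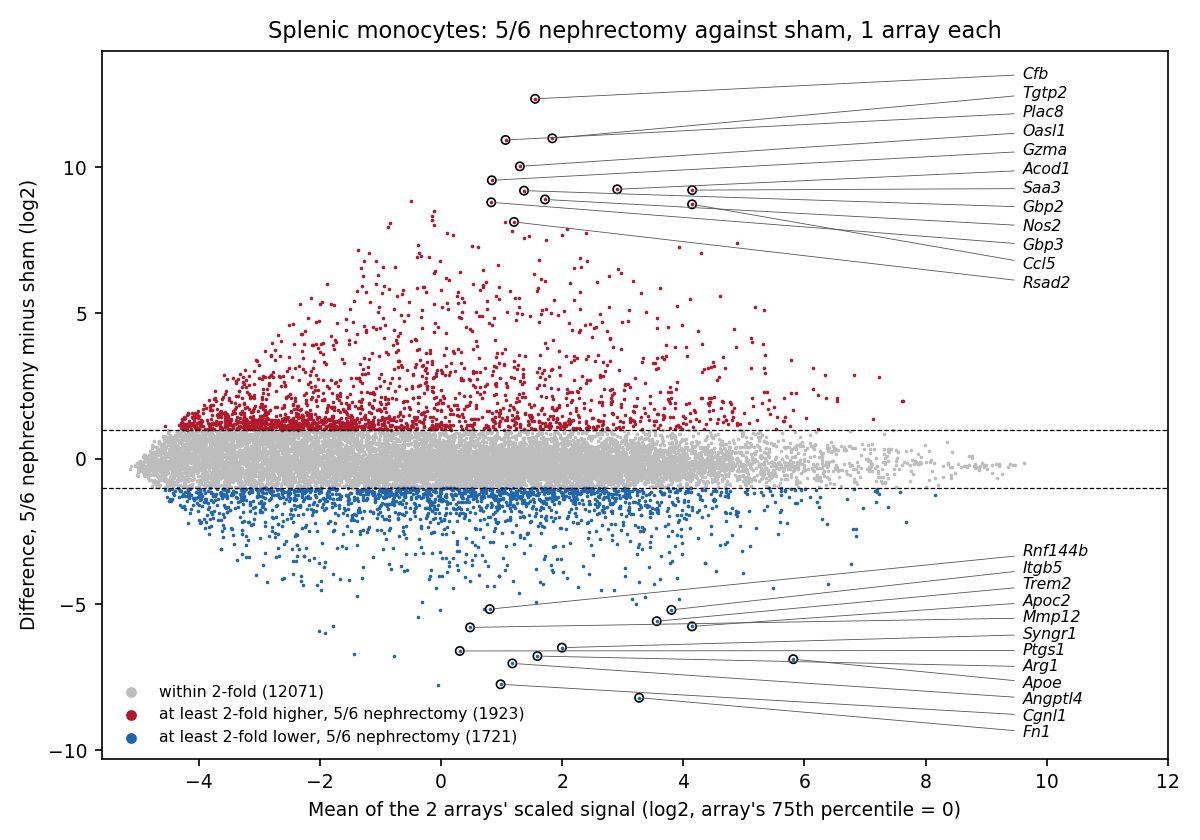
Difference between the arrays (5/6 nephrectomy minus sham, log2, vertical axis) against the mean scaled signal of both arrays (log2, horizontal axis), with 1 point per measured gene and the dashed lines at 2-fold. The circled genes are the 12 per direction with the largest differences under the naming rule, from Cfb at 12.35 to Rsad2 at 8.13 upward and from Fn1 at -8.20 to Rnf144b at -5.16 downward.

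Among the 12 named genes with the largest differences upward, the Cfb probe (chromosome 17, 34993502 to 34993858, mm9) read an intensity of 17.9 on the sham array and 115594 on the 5/6Nx array. Tgtp2 (chromosome 11, 48871837 to 48871896) has a near-identical copy, Tgtp1, so its probe may read both genes. Plac8 (chromosome 5, 100982797 to 100982856), a gene of granulocytes and monocytes, differed by 10.94. Oasl1, an interferon-induced OAS-like protein, differed by 10.03, Rsad2, the antiviral enzyme viperin, by 8.13, and Gbp2 and Gbp3, members of a family of guanylate-binding proteins with similar sequences, by 9.20 and 8.80. Acod1, which makes itaconate and is called Irg1 in the files, differed by 9.25, Nos2, the inducible nitric oxide synthase, by 8.90, the acute phase gene Saa3 by 9.22 and the chemokine Ccl5 by 8.73. Gzma, a granzyme of cytotoxic lymphocytes, differed by 9.55. Where the sham signal lay close to background, the size depends on the background correction. With normexp the fold for Cfb was 1127 in place of 5222, for Plac8 538 in place of 1962 and for Gzma 258 in place of 752. Saa3 and Ccl5, with brighter sham intensities of 319.1 and 377.3, gave 519 in place of 595 and 376 in place of 425.

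Among the 12 named genes with the largest differences downward, Fn1 (chromosome 1, 71632116 to 71632175, mm9) read 72831 on the sham array and 306.3 on the 5/6Nx array, and its 3 probes ranged from -8.25 to -5.47. Apoe (chromosome 7, 20281732 to 20281791), the apolipoprotein E, differed by -6.88, its neighbour in the apolipoprotein cluster Apoc2 by -5.75, Angptl4, an inhibitor of lipoprotein lipase, by -7.03, and Trem2, a lipid-sensing receptor of macrophages, by -5.58. Arg1, the arginase that competes with Nos2 for arginine, differed by -6.77, the macrophage elastase Mmp12 by -5.79 and the cyclooxygenase Ptgs1 by -6.60. Syngr1 differed by -6.48, the integrin subunit Itgb5 by -5.19 and the ubiquitin ligase Rnf144b by -5.16. All 24 of these named genes stayed at least 2-fold apart on their side in every one of the 12 alternatives in which they were measured.

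Among genes well above background on 1 array only, Serpina3g, a serine protease inhibitor, was at least 5150-fold higher on the 5/6Nx array, and Cxcl10, an interferon-induced chemokine, at least 4682-fold. Jchain, the joining chain of secreted antibodies, was at least 1855-fold higher there, Ifit3 at least 1201-fold and Gbp4 at least 738-fold. On the other side Cxcl14, a chemokine, was at least 1308-fold lower on the 5/6Nx array, Acot1, an acyl-CoA thioesterase, at least 201-fold, Ackr3, a scavenging chemokine receptor, at least 38.6-fold, Dusp13 at least 38.0-fold and Bdh2 at least 37.3-fold.

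The sort antigens were bright on both arrays. Itgam, which encodes CD11b (chromosome 7, 135261755 to 135261814, mm9), differed by -0.36, or 0.08 with spike-in scaling, and its other probe by -1.18. Ly6c1 and Ly6c2 (chromosome 15, 74875495 to 74875554 and 74938637 to 74938695), paralogs that the probes may not separate, both differed by 1.98, a 3.9-fold higher signal on the 5/6Nx array.

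The circadian clock list, the transcription factors and repressors of the cellular day rhythm, had a median of -0.32 (percentile 13.3) over 20 measured genes, inside the range of random lists. With spike-in scaling the median was 0.11. The activators and repressors on this list can move in opposite directions, so its median cannot tell whether the clock differed between the arrays. Of the 20 genes 6 were at least 2-fold apart, as were 23.2% of all measured genes. Lower on the 5/6Nx array were Nr1d1, the repressor REV-ERB alpha, at -2.64, Tef at -1.79, Csnk1e at -1.34 and Bhlhe41 at -1.30, and higher were Rora at 1.27 and Hlf at 1.16. Nr1d1, Bhlhe41 and Hlf were dim, and with normexp they differed by -1.41, -0.54 and 0.25. Csnk1e was brighter, but its 3 measured probes ran from -2.96 to -1.34, and with normexp it differed by -2.77. The core activators Clock (chromosome 5, 76639992 to 76640051, mm9) and Arntl, which encodes BMAL1, differed by -0.41 and 0.11. The repressors Per1, Per2 and Per3 differed by -0.36, -0.73 and 0.23, and Cry1 and Cry2 by -0.29 and -0.25. Nr1d2 differed by -0.76, Dbp by -0.42, Ciart by -0.27, Nfil3 by 0.37, Bhlhe40 by 0.26 and Csnk1d by 0.05. For Cry1, Cry2, Per3, Arntl and Csnk1d the probes of the gene differed in sign.

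**Figure D2:**
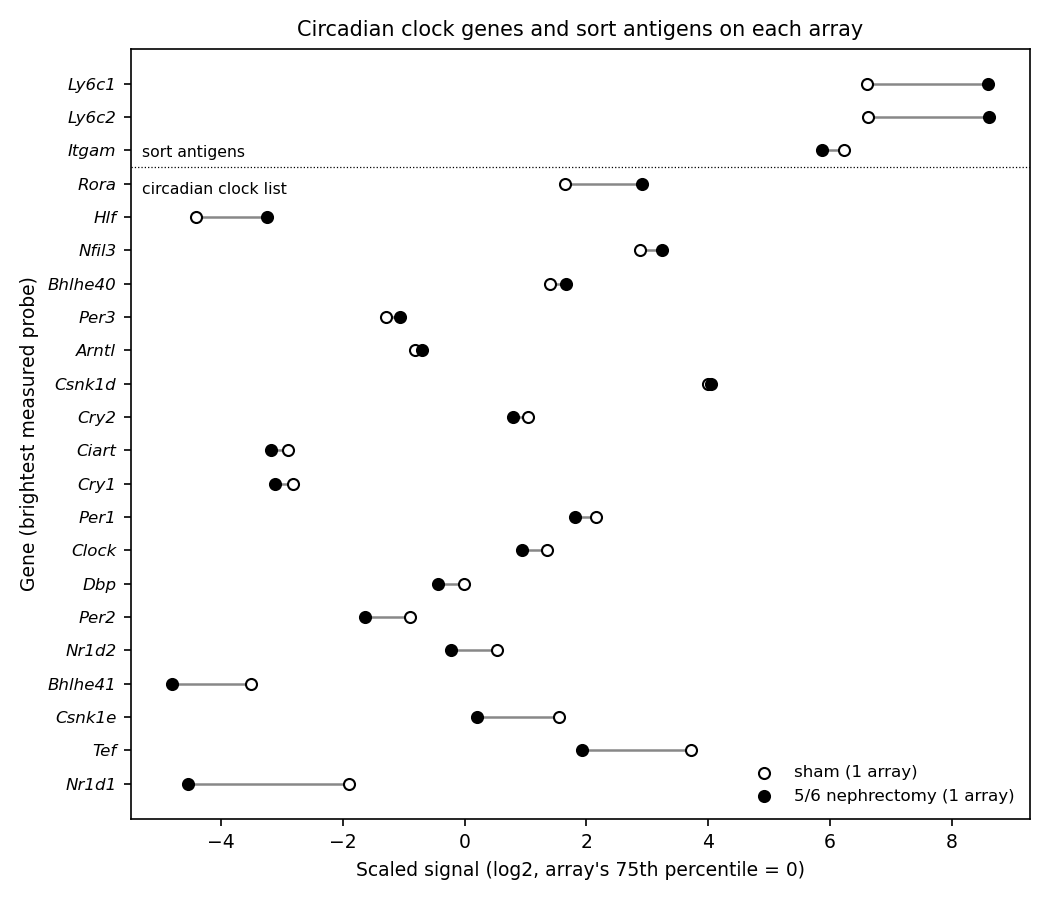
Scaled signal on the sham array (open circles) and the 5/6 nephrectomy array (filled circles) for the sort antigens and 19 of the 20 measured circadian clock genes, each by its brightest measured probe (log2, with each array's 75th percentile at 0). Among the clock genes the differences ran from -2.64 for Nr1d1 to 1.27 for Rora.

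Inflammatory cytokines and chemokines had a median of 3.75 (percentile 100), with 15 of 23 measured genes at least 2-fold higher, 1 lower and 7 more above background on the 5/6Nx array only. The largest differences after Nos2 and Ccl5 were in the monocyte chemoattractant Ccl7 at 7.67 and in Il1b, the interleukin-1 beta, at 7.57. All 23 measured interferon-stimulated genes were at least 2-fold higher, with a median of 5.70 (percentile 100), and the other 4 were above background on the 5/6Nx array only. Ifit1 differed by 8.49 and Mx1, an antiviral GTPase, by 8.11. Feedback regulators and targets of NF-kappaB had a median of 2.19 (percentile 100), with 17 of 20 higher, led by Traf1 at 6.35, Cd40 at 5.87 and the adhesion molecule Icam1 at 4.11. Antigen presentation genes of MHC class II had a median of 2.65 (percentile 100), with 8 of 11 higher, among them H2-Ab1 at 4.60, H2-Eb1 at 4.48 and Ciita, their master regulator, at 4.51. The markers of T cells and NK cells were higher on the same array, with list medians of 4.71 and 3.35. B cells and conventional dendritic cells, which carry MHC class II, had marker list medians of 0.90 and 1.65. With one-array genes added at their bound, the medians were 4.67 for cytokines and chemokines, 6.37 for interferon-stimulated genes and 3.51 for MHC class II genes.

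Among pattern recognition receptors 9 of 21 were higher and 4 lower, with a median of 0.30 (percentile 99.5). Clec4e, the receptor Mincle, differed by 5.24, Nod1 by 4.95 and Nod2 by 3.63. Migration receptors and adhesion molecules had 8 of 20 higher and 4 lower, with a median of 0.37 (percentile 99.8). The fractalkine receptor Cx3cr1 differed by -4.24, Ccr7, which guides cells to lymphoid tissue, by 4.09, and the integrin subunit Itgal by 3.03. Immediate early and dissociation stress genes had a median of 0.61 (percentile 100), with 11 of 27 higher and 3 lower, led by Dusp2 at 4.97 and Egr2 at 4.84. Cell cycle genes had a median of 0.54 (percentile 99.7), with 7 of 23 higher and none lower, led by Mki67 at 3.55 and Ccne1 at 2.25. Over genes brighter than the median gene the medians of pattern recognition and migration were only 0.029 and 0.058. With bounds added that of pattern recognition was 0.167, close to 0.171, the upper end of its random range, which was drawn without bounds. The T cell and NK cell markers were higher on the same array.

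The matrix and fibrosis list had a median of -0.30 (percentile 14.4), inside the random range, with 9 of 23 genes lower and 4 higher. With spike-in scaling the median was 0.13. Besides Fn1 and Mmp12, the largest differences were in the collagenase Mmp8 at -3.97 and in the growth factor Pdgfa at -3.89. Genes of classical monocytes went both ways, with 6 of 12 higher and 3 lower and a median of 0.28 (percentile 97.3). The median was -0.52 over genes brighter than the median gene and -0.21 with the mean over a gene's probes. Among its members with large differences were Plac8, Fn1 and Hp, the haptoglobin, which differed by 6.26. Non-classical monocyte markers had a median of 0.98 (percentile 99.95), with 6 of 12 higher and 2 lower, from Cd300e at 5.34 to Cx3cr1 at -4.24.

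Antioxidant genes and targets of the transcription factor Nrf2 were lower as a group, with a median of -1.29 (percentile 0). Of 24 genes 16 were at least 2-fold lower and 2 higher. Gstm1, a glutathione transferase, differed by -3.52, Cat, the catalase, by -3.31, and Gclc, the rate-limiting enzyme of glutathione synthesis, by -3.02, while the mitochondrial dismutase Sod2, also a target of NF-kappaB, differed by 3.28. Glucocorticoid-responsive genes had a median of -1.03 (percentile 0.01), with 7 of 13 lower and 3 higher, among them Anxa1 at -2.37, Mt1 at -2.29 and the decoy receptor Il1r2 at 2.82. Genes of glycolysis and hypoxia had a median of -0.54 (percentile 0.21), with 8 of 26 lower and 2 higher. The oxygen sensor Egln3 differed by -4.03, the glucose transporter Slc2a3 by 3.36 and Vegfa by -2.60. Lipid efflux and uptake genes had a median of -0.47 (percentile 2.26), with 8 of 21 lower and 6 higher. Here the scavenger receptor Cd36 differed by -4.99 and the lipid droplet protein Plin2 by -3.60, whereas Marco, another scavenger receptor, differed by 7.05. With spike-in scaling the medians of these 4 lists, in the order given, were -0.86, -0.60, -0.11 and -0.0397, so that the last 2 came close to 0. With the mean over a gene's probes the glucocorticoid-responsive median was -0.53. As for the lists above, T cell and NK cell markers were higher on the 5/6Nx array.

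Several lists lay inside the random range. The retinoid list had a median of -0.47 (percentile 4.6), with Dhrs3 at -3.91 and Tgm2 at 1.99, and a median of 0.10 with the looser filter on dim probes and 0 without one. For aryl hydrocarbon receptor targets the median was -0.65 (percentile 2.98), led by Ugt1a6a at -2.14 and Nqo1 at -1.65, with a median of 0 without a filter on dim probes and the other sign over genes brighter than the median gene. NADPH oxidase genes had a median of 0.24 (percentile 93.2), with Duox2 at -3.27 and Cybb at 3.05, and the other sign with the looser filter, without a filter and, at -0.07, with bounds added. The unfolded protein response had a median of 0.04 (percentile 92.3), led by Chac1 at 3.25 and Herpud1 at 1.52, and turned with median scaling. Cholesterol synthesis genes, with Stard4 at -0.97 and Insig1 at -0.96, had a median of -0.43 (percentile 6.47), and 0.01 with spike-in scaling. The median of ribosomal proteins was -0.31 (percentile 7.91), with none of 31 genes 2-fold apart and Rpl10 and Rps2 at -0.77 and -0.74, and its sign turned with quantile, loess and spike-in scaling. Receptors of the renin-angiotensin system and of hormones altered in kidney disease had a median of 0.14 (percentile 58.7), led by Fgfr1 at 1.14 and Nr3c2 at 1.07, and turned in 3 alternatives. Oxidative phosphorylation genes lay just above the range at 0.05 (percentile 97.6), with 1 of 30 genes 2-fold apart, Cycs at 1.24, while Ndufa4 differed by -0.76, and the sign turned with median scaling and with the mean over a gene's probes.

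Marker lists of other cell types were measured in the same way. T cell markers had 12 of 15 measured genes higher, none lower, and 2 more above background on the 5/6Nx array only (percentile 100). Cd3g differed by 6.31, Cd3d by 6.19, Cd8b1 by 5.78 and the kinase Lck by 5.50. With normexp the T cell median was 3.27. All 5 measured NK cell markers were higher (percentile 99.99), including Il2rb at 7.66 and Tbx21 at 3.35, and the other 7 were above background on the 5/6Nx array only, for a median of 4.22 with bounds added. The NK cell median was 2.90 with normexp and 5.51 over genes brighter than the median gene. Conventional dendritic cell markers had a median of 1.65 (percentile 99.96), with Itgae at 4.43, Batf3 at 4.28 and Clec10a at -4.12. This median was 0.24 over genes brighter than the median gene, 0.95 without a filter on dim probes and 1.30 with bounds added. B cell markers had a median of 0.90 (percentile 98.8), led by Cd79b at 1.92 and Bank1 at 1.38, with 5 more above background on the 5/6Nx array only. With normexp the median was 0.56, and Bank1 differed by 0.56. Plasma cell markers had a median of 0.74 (percentile 96.05), with Irf4 at 4.41 and Sdc1 at -2.10, and 4 more, Jchain among them, on the 5/6Nx array only, which put the median at 3.14 with bounds added, and the alternatives ran from 0.30 to 4.41. Neutrophil markers had a median of 0.51 (percentile 98.7), with Lcn2 at 7.31, Ly6g at 4.53 and Mmp8 at -3.97. Of 9 basophil and mast cell markers, 2 were measured, Fcer1a at 2.32 (0.88 with normexp) and Hdc at 1.48, and 7 were above background on the 5/6Nx array only.

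Red pulp macrophage markers went both ways, with a median of 0.26 (percentile 96.35), Spic at 5.53 and Trf at -4.08, and their sign turned over genes brighter than the median gene and with the mean over a gene's probes. Platelet and megakaryocyte markers had a median of -0.47 (percentile 7.34), with Pf4 at -4.31, Treml1 at -3.81 and Clec1b at 3.59, and a median of 0.03 without a filter on dim probes and 0.06 with bounds added. Granulocyte-monocyte progenitor markers had a median of 0.72 (percentile 86.8), with Cd34 at -2.93, Elane at -1.66, Mpo at 1.35 and Kit at 1.11. Of the 5 measured markers 3 were positive, and 2 more were above background on the 5/6Nx array only. The list turned over genes brighter than the median gene, where Elane alone gave -1.66. Plasmacytoid dendritic cell markers had a median of 0.27 (percentile 86.1), with Lair1 at 3.12 and Ccr9 at 0.85, and turned there too. Eosinophil markers had a median of 0.81 (percentile 83.6), with Ear1 at 1.19 and Il5ra at 0.81. Erythroid markers had a median of 0.27 (percentile 84.75), with the paralogs Hba-a1 and Hba-a2 both at 2.70, and the alternatives ran from 0 to 2.70. Endothelial and stromal markers had a median of 0.70 (percentile 91.8), with Kdr at 4.45 and Dcn at 1.33. The alternatives ran from 0 to 4.45, the upper end being the value of Kdr alone.

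**Figure D3:**
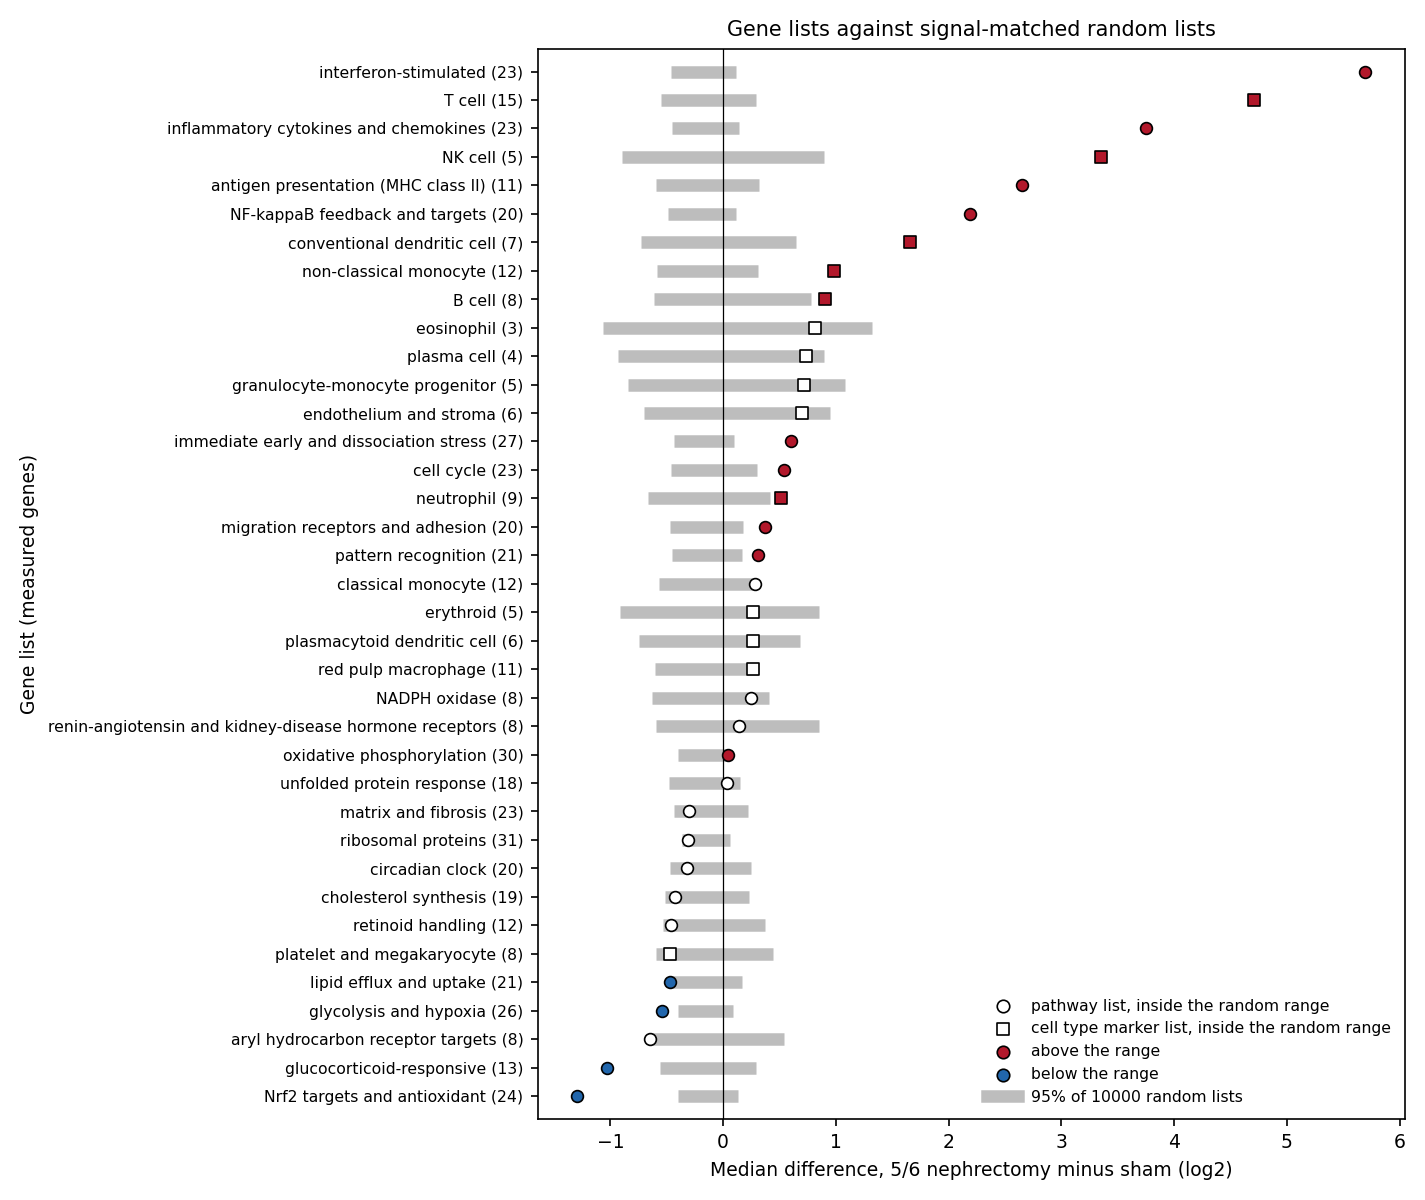
Median difference (5/6 nephrectomy minus sham, log2, horizontal axis) of gene lists fixed in advance, with the number of measured genes in brackets. Grey bars span 95% of 10000 random lists matched on signal, circles are pathway lists, squares are cell type marker lists, and filled symbols lie above (red) or below (blue) the bar. The interferon-stimulated list at 5.70 and the T cell list at 4.71 lay farthest above their bars, and the Nrf2 and antioxidant list at -1.29 farthest below.

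These differences are between single arrays, so differences between animals, sorts or labelling reactions cannot be told apart from an effect of the operation. Where a gene was close to background on 1 array, the size of its difference depended on the background correction. With normexp Duox2 differed by -1.54 in place of -3.27, Slc2a3 by 1.82 in place of 3.36 and Il1r2 by 1.11 in place of 2.82. Nqo1 at -0.94, Dcn at 0.62 and Nr3c2 at 0.39 fell under 2-fold there.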

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

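Both arrays carry ERCC control probes, which match synthetic RNAs that no label names as added, and some of them gave a signal. Of 96 such probes, 4 were well above background on the sham array and 7 on the 5/6Nx array. The highest mean intensity of such a probe was 47.3 on the sham array and 85.5 on the 5/6Nx array. Of the 12 named genes with the largest differences upward, 7 had a sham intensity at or below 47.3, and of the 12 downward, 2 had a 5/6Nx intensity at or below 85.5. Among all genes at least 2-fold apart, this held for 582 of 1923 upward and 442 of 1721 downward. No biological explanation was tested for the signal of these probes.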

How the results depend on the processing

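The setting that adds genes found on 1 array only at their bound was chosen after the data were seen. No paired analysis was possible because each group has 1 array. The median of all measured genes was -0.12, and it was -0.27 with median scaling, 0.05 with cyclic loess, 0.31 with spike-in scaling and 0 without a filter on dim probes. The counts of genes at least 2-fold apart stayed within 1.5 times of 1923 higher and 1721 lower except as follows. With normexp 1164 genes were higher, with spike-in scaling 3327 were higher and 857 lower, and among genes brighter than the median gene, a smaller set, 859 were higher and 1050 lower. In each of the 12 alternatives none of the genes at least 2-fold apart in the main setting was 2-fold apart on the other side.

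The inflammatory cytokine and chemokine list kept its sign throughout. Its median of 3.75 became 3.31 with normexp, 3.92 with cyclic loess, 4.18 with spike-in scaling, 4.56 and 4.64 with the looser filter on dim probes and without one, and 4.67 among brighter genes, and also 4.67 with bounds added. The classical monocyte median of 0.28 became 0.56 with cyclic loess, 0.71 with spike-in scaling, -0.52 among brighter genes and -0.21 with the mean over a gene's probes. The matrix and fibrosis median of -0.30 became 0.13 with spike-in scaling, -0.0376 without a filter on dim probes and -1.30 among brighter genes. The clock median of -0.32 became 0.11 with spike-in scaling. The oxidative phosphorylation median of 0.05 turned to -0.10 with median scaling and -0.0423 with the mean over a gene's probes. The spike-in and median scalings add one constant to every gene, and the filters change which genes are measured. The cause of the other shifts was not tested. Over all alternatives, a primary list moved by less than 1 SD of its matched random lists in 37 of 52 cases. For the other lists this held in 320 of 441 cases, not counting the 2 in which a list called apart from random lists turned its sign. The sign turned in 4 of the 52 cases and in 21 of the 441, of which 2, those of oxidative phosphorylation, were of a list called apart from random lists.

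Of 181 named measured genes, 140 were at least 2-fold apart. None of these 140 turned its sign in an alternative in which it was measured, and 20 fell under 2-fold in at least 1 of them. Differences of genes near background on 1 array are limited by the signal over background there, and bounds stand in for genes below it.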

Other observations

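The tests of array scaling and the comparison of T cell with B cell markers were chosen after the results were seen, and so was the SD between members as the spread of a list. The other tests rest on gene lists whose members' values had not been looked at when the predictions were written, though related genes had.

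Genes of lysosomes and phagocyte storage, a list outside the fixed ones, were lower on the 5/6Nx array. Their median difference was -1.56 (percentile 0 of the random lists), and 10 of 18 were at least 2-fold lower and none higher. The tetraspanin Cd9 differed by -3.34, Gpnmb, a protein of lipid-laden macrophages, by -2.67, the lysosomal lipase Lipa by -2.65 and the cathepsins Ctsd and Ctsl by -2.17 and -2.06. On the same array the T cell and NK cell lists were higher, with medians of 4.71 and 3.35. Ifng, which encodes interferon gamma and was picked after its value was seen, was well above background on the 5/6Nx array only, with a bound of 9.48 in log2 units.

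Interferon-stimulated and cytokine genes were higher on the 5/6Nx array. Array scaling as the whole cause is argued against by the lowest median of the interferon-stimulated list over the scaling and background alternatives, 5.40. Lymphocytes in the sort as the only source are argued against by 14 inducible genes of myeloid cells, whose 11 measured members had a median of 3.82, with Slc7a2 at 7.17. The other 3 were above background on the 5/6Nx array only, among them Hcar2 with a bound of 8.05. Which myeloid cells carried these genes was not tested. Neutrophil markers had a median of 0.51 (percentile 98.7), with 4 of 9 measured genes at least 2-fold higher and 1 lower. A response to interferon gamma is a candidate explanation that remains open, as 17 measured GTPase, immunoproteasome and related genes had a median of 4.70, although type I interferon induces many of them too. An effect of the operation, an infection in single animals and the handling of the cells stay untested with 1 array per group.

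T cell and NK cell markers were higher on the 5/6Nx array. If the other cell types kept their proportions to each other, a lower share of monocytes would raise the markers of each of them alike. The medians of the T cell and B cell lists, bounds included, lay 3.35 apart, where an equal rise would put them together. Medians with bounds were nearer the T cell median of 4.71 for NK (4.22), basophil and mast cell (3.61) and plasma cell (3.14) markers. Others, such as the erythroid and platelet lists at 0.71 and 0.06, lay farther from it. The gap of 3.35 is only slightly larger than 3.03, the member SDs of both lists combined as the root of their summed squares. Many of the B cell genes were dim, so this comparison cannot decide the question. T and NK cells in the sorted sample may account for the pattern, as 10 measured genes of these cells outside the fixed lists had a median of 4.24, and 8 more were above background on the 5/6Nx array only. The T cell marker Cd3d read an intensity of 4904 and the NK cell marker Gzma 26732 there. A gate on CD11b removes most T cells, while NK cells carry CD11b, and how the gate was set is not given in the sources used here.

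The glycolysis and hypoxia list was lower on the 5/6Nx array, and so was Arg1, a gene picked after its value was seen. How far the glycolysis and hypoxia list lay below 0 depends on array scaling. Its median of -0.54 was -0.11 with spike-in scaling, within 1 SD of random lists (0.121) from 0. Spike-in scaling adds one constant to every gene, so it leaves the list's place among random lists, percentile 0.21, unchanged. Array scaling thus stays open for a fall below 0, but one constant cannot set the list below the random lists. Alternative activation on the sham array remains open. The 8 measured genes of its list had a median of 0.52, above the value of -0.5 set in advance as its limit, and 6 of them were positive. They went both ways, with Mrc1 at -2.44 and 3 genes 2-fold higher. A further 2 were above background on the 5/6Nx array only, for a median of 0.93 with bounds added. The SD between the 8 measured genes was 2.31, more than the distance to that limit. Arg1, at -6.77, is part of the pattern to be explained, so it lends this explanation no further weight. A hypoxia response on the sham array remains open, since 14 genes outside the fixed lists had a median of -0.52, between the values of -1 and -0.5 set in advance and inside the range of random lists, with 4 genes lower and 2 higher. An effect of the operation, and a different mix of monocytes and macrophages in the sorts, stay untested.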
